A study of Sus scrofa with 16 samples.

How the data were processed

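The deposited table gave 1 intensity per probe and array on a linear scale, for 1015 probes on each of 16 arrays, and every column of values was used (0 columns were left out). Per the labels, total RNA was extracted from embryos of 4 stages in 4 samples each, amplified, converted to a target labelled with phosphorus-32 and hybridised to a membrane carrying cDNA products. How the authors scanned the membranes, subtracted background and normalized the deposited intensities is not given in the sources used here. The deposited values ran from 0.120 to 805 with no missing value. On each array they lay on a regular grid, with a commonest step of 0.815 to 1.67 and 160 to 256 distinct values, and up to 8 probes shared the maximum of an array, so the brightest probes can be saturated. No background or blank feature was known, so dim probes have no measured floor.

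The 16 array medians spanned 0.185 on the log2 scale, below a fixed limit of 0.2, and the table was taken as already normalized: values were transformed to log2 with no pseudocount and no further normalization. Probe 357 held the same value on every array and was left out, leaving 1014 probes. Of the 1015 probes, 676 had 1 gene symbol in the platform annotation, 15 had several and 324 had none. The 676 probes named 637 genes, 34 of them by several probes. Of 674 probes with a single Entrez identifier, 668 were found in the RefSeq gene table, which changed 0 symbols. Probes with several symbols or none are given by number. A gene with several probes is represented by the probe with the highest mean. Samples were grouped by the stage in their titles, and the replicate number also came from the titles.

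A linear model with 1 mean per stage was fitted to all 16 arrays with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), followed by an F test over the 4 stages and 6 contrasts between stages. Tests were two-sided and p-values were adjusted by Benjamini-Hochberg over the 1014 probes, with a threshold of 0.05. Means and SDs are of linear intensities, and fold differences are taken from the log2 fit and hence compare geometric means. Of 26 fixed gene lists, 22 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over all 132 pairs of list and contrast, with an estimated correlation and fry as alternatives. The other 4 lists are given as values. The grouping, the limit on medians, the tests, the lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. Named genes followed a fixed rule: for the 3 adjacent steps and for filamentous minus small spherical, up to 10 higher and 10 lower genes past the threshold, or the 5 with the smallest p where fewer than 5 named genes passed, as was so in each; up to 4 members of each list with the largest F; and 21 genes chosen in advance, of which IL1B, POU5F1, TTR, ACTB, STAT3 and S100G were not measured by a probe with a single symbol.

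Alternatives were median centring, quantile and cyclic loess normalization, leaving out the dimmest 25% of probes, an offset before log2, the replicate number as a block, only the 2 stages compared, array weights, a variance trend with a robust prior, and each array left out in turn. In 1 contrast, large minus small spherical, all 4 pairs of arrays with the same number deviated together (correlations of 0.219 to 0.495), so the blocked value is given beside it where it changed a call; in the 5 others at least 1 pair stayed under 0.1. This check by contrast was made after the blocked calls had been seen. Alternatives added after the data were seen were a batch term for the arrays numbered 1, the 12 arrays numbered 2 to 4 alone, removal of a smooth trend along probe number (loess, span 0.1), the removal of both arrays that lay toward another stage, and a contrast of the first step with the later change. The fit was tested on simulated data: 20 sets of 1014 probes with the means and spreads of the real ones, in which 200 probes were changed between filamentous and small spherical arrays. It recovered 18.6% of probes changed by 0.5 on the log2 scale, 63.4% of those changed by 1 and 93.0% of those changed by 2, and 3.72% of the calls were unchanged probes. The simulated noise was normal and independent between probes and arrays, without the shared deviations, value grid or shared maxima of the real arrays. Recovery also depends on how many probes change, here 200 of 1014. These shares therefore describe the simulated setting and need not hold for the real data. Plots were drawn with matplotlib 3.10.9.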

Results

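Messenger RNA was profiled in whole pig embryos (conceptuses, the embryo with its extraembryonic membranes) at the time they elongate in the uterus before attachment. Amplified RNA was labelled with phosphorus-32 and hybridised to a cDNA macroarray, a membrane spotted with products of cDNA clones. The 16 arrays fell into 4 stages by the shape and length of the embryo: small spherical (1 to 5 mm), large spherical (6 to 11 mm), tubular (13 to 45 mm) and filamentous (over 100 mm), with 4 arrays each. The table held 1015 probes, and median intensity per array lay between 62.8 and 71.4. Spearman correlations across probes were 0.841 to 0.96 within a stage and 0.794 to 0.974 between stages. The number of arrays limits the precision. Nothing in the labels says that the 4 arrays of a stage came from separate animals or litters, so the p-values measure only the spread between these samples. The 4 arrays numbered 1, 1 per stage, stood apart from most of the others on the first principal component, so values from the other 12 arrays are given beside the leading results. Small spherical replicate 3 and filamentous replicate 1 lay toward other stages, and values without both are given where they matter.

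**Figure D1:**
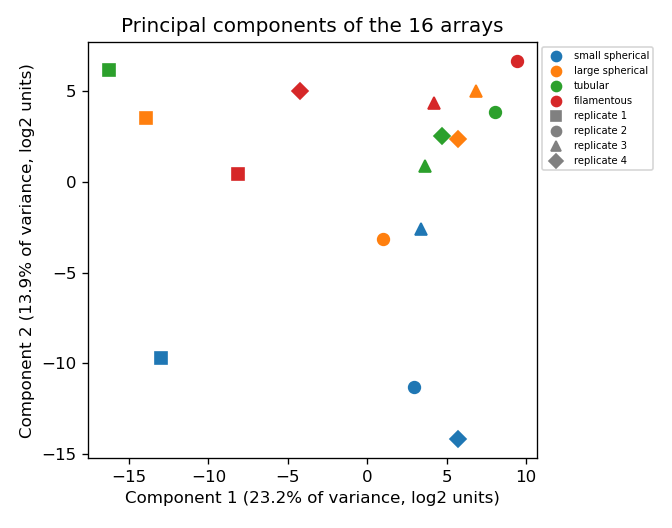
Scores of the 16 arrays on the first principal component (x axis, 23.2% of the variance) and the second (y axis, 13.9%), from log2 intensities, with colour for the stage and symbol for the replicate number. The 4 replicate 1 arrays lie between -16.3 and -8.17 on component 1, and small spherical replicate 3 lies at -2.58 on component 2, where the other small spherical arrays lie between -14.2 and -9.72.

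The first comparison asked which transcripts differed between any of the 4 stages. STAR, which carries cholesterol into mitochondria for steroid synthesis, differed between stages (adjusted p = 0.000617, limma F test), as did TGFB3, a secreted transforming growth factor (adjusted p = 0.0106). STAR averaged 40 ± 7.89 in small spherical, 135 ± 38.6 in large spherical, 160 ± 19.4 in tubular and 153 ± 34.3 in filamentous embryos (intensity, SD, n = 4). All 12 arrays of the later stages lay above the highest small spherical array for STAR, and 11 of 12 did for TGFB3. The other probes past the threshold had no gene name here: probe 538 (adjusted p = 0.0222) and probe 1010 (adjusted p = 0.00933). In all, 4 of 1014 probes passed, and 105 had an unadjusted p below 0.05 where chance gives 50.7. The count was 1 without small spherical replicate 2, 13 without small spherical replicate 3, and 2 without small spherical replicate 4.

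Between small and large spherical embryos, the first step of growth, STAR rose 3.29-fold (log2 difference 1.72 ± 0.23 SE, adjusted p = 0.00207). TGFB3 rose from an intensity of 5.86 ± 5.86 to 47 ± 14 (log2 3.41 ± 0.62, adjusted p = 0.0212). The small spherical values of TGFB3 were dim (1.79, 3.2, 14.5 and 3.91), so its fold is imprecise, and its log2 difference ran from 1.94 (with an offset before log2) to 4.00 over the alternatives. Each of the 4 large spherical arrays exceeded every small spherical array for both genes. Probes 954 and 1010 also rose, each past the threshold in 23 of 29 alternatives, and nothing passed in the lower direction. Neither passed without small spherical replicate 2 or 4 or large spherical replicate 2, 3 or 4 (adjusted p of 0.0551 to 0.113), nor did probe 954 without small spherical replicate 1 (0.0791). The count was 4 of 1014 probes by limma, with 95 at an unadjusted p below 0.05. On the 12 arrays numbered 2 to 4, STAR differed by 1.92 ± 0.21 (adjusted p = 0.00203) and TGFB3 by 3.25 ± 0.44 (adjusted p = 0.00485), and on the arrays numbered 1, STAR read 38.7 and 84.6. Single arrays moved the count, which was 26 without small spherical replicate 3, 11 without filamentous replicate 1, and 1 without small spherical replicate 2 or 4 or large spherical replicate 2, 3 or 4. TGFB3 did not pass without small spherical replicate 1 (adjusted p = 0.0639), 2 (0.103) or 4 (0.067), without large spherical replicate 2 (0.0699), 3 (0.0708) or 4 (0.073), or with only these 2 stages in the fit (0.0608), over a range of 6.76e-06 to 0.103.

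**Figure D2:**
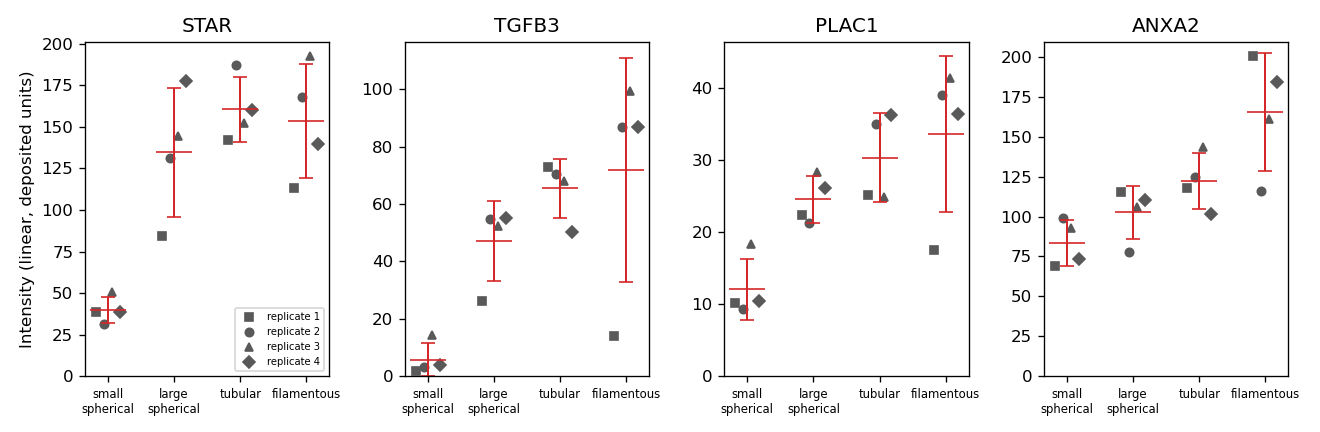
Intensity (linear scale as deposited, y axis) of STAR, TGFB3, PLAC1 and ANXA2 on each of the 16 arrays by stage (x axis), with grey symbols for single arrays (shape gives the replicate number) and red bars for the mean ± SD of 4 arrays. STAR lies between 31.8 and 50.8 in small spherical embryos and between 84.6 and 193 on the 12 other arrays, and filamentous replicate 1 lies at 14.2 for TGFB3 and 17.6 for PLAC1, below the other filamentous arrays.

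Genes of steroid synthesis were higher as a group in large than in small spherical embryos. All 8 measured members of this list had a positive difference, with a median of 0.86 on the log2 scale (camera, adjusted p = 6e-08, and adjusted p = 0.0811 with an estimated correlation). STAR alone passed over all probes. When adjusted over the list alone 6 of the 8 passed: STAR, CYB5A, CYP11A1, HSD17B4 (0.89), HSD17B12 (0.53) and CYB5B (0.99), but not CYP17A1 or CYP19A1. The list took every measured symbol that begins with HSD17B or CYB5, so membership alone does not show a role in steroid synthesis. CYP11A1, the side-chain cleavage enzyme that makes pregnenolone, read 40.9 ± 12.9 and 81.5 ± 28.6 in the 2 stages, a log2 difference of 0.99 ± 0.31 that did not pass (adjusted p = 0.173). CYB5A, a cytochrome b5 that aids the lyase reaction of CYP17A1, differed by 0.83 ± 0.18 (adjusted p = 0.0545), and CYP19A1, the aromatase that makes oestrogens, by 0.37 ± 0.18 (adjusted p = 0.62). The median of the list was 0.89 on the 12 arrays numbered 2 to 4 (adjusted p = 1.85e-07) and 0.97 without small spherical replicate 3 and filamentous replicate 1 (adjusted p = 6.44e-07).

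**Figure D3:**
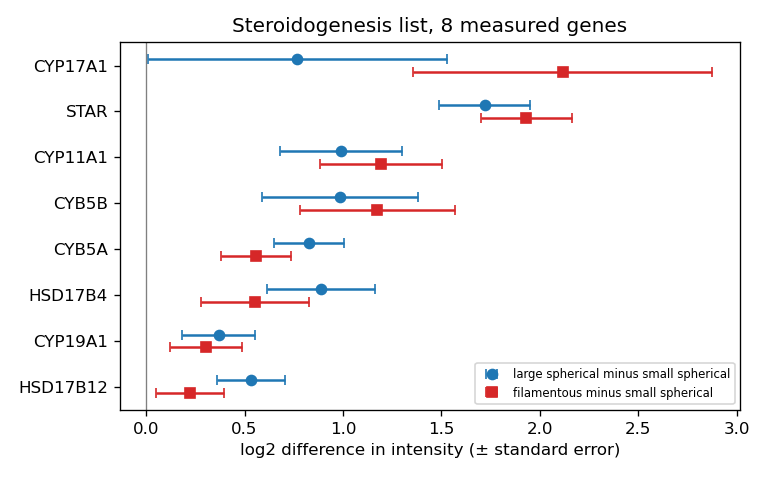
Log2 difference in intensity (x axis, ± standard error of the limma fit) from small spherical embryos for the 8 measured genes of the steroidogenesis list (y axis), in large spherical embryos (circles) and filamentous embryos (squares). All differences are above 0, and STAR has the smallest adjusted p in both, 0.00207 and 0.000499.

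Other named genes of this step did not pass over the 16 arrays. ACSL3, which activates long-chain fatty acids, read 35.2 ± 11.2 and 106 ± 24.4 (log2 1.62 ± 0.35, adjusted p = 0.0545). It passed on the 12 arrays numbered 2 to 4 (adjusted p = 0.0491), with the replicate number as a block (0.0138), with a batch term for the arrays numbered 1 (0.0055), and without small spherical replicate 3 (0.0323), tubular replicate 3 (0.0488) or filamentous replicate 1 (0.0169). CYB5A passed on the 12 arrays (0.0172), with the batch term (0.032), and without small spherical replicate 1 (0.00554) or filamentous replicate 1 (0.0491). IL12A, a subunit of interleukin 12, read 2.47 ± 0.756 and 10.6 ± 3.8 (adjusted p = 0.0545). It passed without tubular replicate 3 (0.0339) or filamentous replicate 3 (0.0278) or 4 (0.0354). It also passed with cyclic loess normalization (0.0491), only these 2 stages in the fit (0.0328) or the trend along probe number removed (0.033). Its small spherical values were dim (3.03, 3.2, 1.91 and 1.73), so its rise is imprecise. PLAC1, a gene of placental trophoblast, read 12.1 ± 4.2 and 24.6 ± 3.26 (log2 1.07 ± 0.28, adjusted p = 0.0887). SMAD4, a mediator of TGF beta signals, read 94.2 ± 5.47 and 145 ± 15.4 (adjusted p = 0.0669), CTSC, a lysosomal protease, 40.7 ± 6.56 and 89.5 ± 18.2 (adjusted p = 0.0669), and SOD1, a superoxide dismutase, 103 ± 27.5 and 177 ± 26.7 (adjusted p = 0.0878). Of the 10 measured genes of growth factor and TGF beta signalling, TGFB3 passed over all probes and 2 passed when adjusted over the list alone. The list was not called (camera, adjusted p = 0.894), and its median of -0.09 had the opposite sign to the test's direction.

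No probe passed between large spherical and tubular embryos by limma, with 33 at an unadjusted p below 0.05 where chance gives 50.7. STAR differed by 0.30 ± 0.23 and TGFB3 by 0.52 ± 0.62 on the log2 scale (adjusted p = 0.999 for each). The 5 named genes with the smallest p did not pass. IL12B read 4.67 ± 4.16 and 0.673 ± 0.695 (adjusted p = 0.7), and CD3E, a T cell receptor component and the 1 measured marker of maternal blood, 2.85 ± 1.21 and 1.32 ± 0.745, both dim. ARID1A, a chromatin remodelling subunit, read 9.9 ± 1.03 and 18.4 ± 6.62, CENPF, a kinetochore protein, 152 ± 19.8 and 111 ± 23.8, and DLD, a subunit of mitochondrial dehydrogenase complexes, 50 ± 18.5 and 72 ± 9.25 (adjusted p = 0.999 for each). None of the 22 gene lists tested was called in this contrast.

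Between tubular and filamentous embryos, genes of glycolysis and lactate were higher as a group in filamentous ones, with all 5 measured members positive and a median log2 difference of 0.40 (camera, adjusted p = 0.00927, and adjusted p = 0.097 with an estimated correlation). Within the list, GAPDH read 68.5 ± 3.37 and 96.1 ± 12.8, ENO1 62.5 ± 8.25 and 82.4 ± 8.61 and LDHB 133 ± 43.6 and 176 ± 47.7. The other members were SLC2A1 and SLC2A3. In small spherical embryos GAPDH read 79.8 to 97.7, LDHB 128 to 192 and ENO1 51 to 67.9. Each small spherical value of GAPDH exceeded its tubular ones, so its difference need not be a rise over all stages. No member passed over all probes (adjusted p = 0.994 for GAPDH), and 1 of the 5 passed when adjusted over the list alone. The 23 cytosolic ribosomal protein genes had a median difference of 0.18, with 16 positive and 7 negative (camera, adjusted p = 0.0296, and adjusted p = 0.391 with an estimated correlation). RPS2 read 224 ± 21 and 303 ± 54.2, and no member passed over all probes or when adjusted over the list alone. Other named genes that did not pass were IL12B, BNIP3L, a mitophagy receptor (153 ± 19.4 and 218 ± 17.8), TF, transferrin (25.3 ± 9.56 and 11.5 ± 5.47), and APOA1, an apolipoprotein (105 ± 16.7 and 172 ± 44.5). No probe passed by limma, with 34 at an unadjusted p below 0.05. On the 12 arrays numbered 2 to 4 the glycolysis list had an adjusted p of 0.00504 and the ribosomal list, not called, one of 0.0638. The median of the glycolysis list was 0.22 without tubular replicate 2 and 0.25 without filamentous replicate 1. The ribosomal list was not called without tubular replicate 3 (median 0.12, adjusted p = 0.215), filamentous replicate 1 (0.0869) or 2 (0.137). Nor was it called with the trend along probe number removed (0.0599), with the replicate number as a block, or by fry (0.198). It was called in 22 of 31 alternatives, with an adjusted p of 0.00593 to 0.391.

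Across the whole interval, from small spherical to filamentous embryos, STAR rose 3.81-fold (log2 1.93 ± 0.23, adjusted p = 0.000499) and TGFB3 rose by 3.75 ± 0.62 (adjusted p = 0.00765), with 2.29 to 5.01 over the alternatives. PLAC1 rose 2.75-fold, to 33.7 ± 10.9 (1.46 ± 0.28, adjusted p = 0.0159). ANXA2, a membrane-binding annexin, rose 1.96-fold, from 83.6 ± 14.5 to 165 ± 36.9 (0.97 ± 0.20, adjusted p = 0.0309). STAR and ANXA2 were above the highest small spherical array on all 4 filamentous arrays, and TGFB3 and PLAC1 on 3 of 4, the exception being replicate 1. ADSL, an enzyme of purine synthesis, did not pass (163 ± 88.3 and 397 ± 147, adjusted p = 0.0847), but did without small spherical replicate 3 (adjusted p = 0.0103). It read the maximum of the array on filamentous replicates 1 and 3, where values can be saturated, so its mean and test are imprecise. By limma 9 of 1014 probes passed, 8 higher and 1 lower, with 148 at an unadjusted p below 0.05. Among probes without a gene name, 458, 538, 540 and 1010 rose and 478 fell. Probe 538 passed in all 28 alternatives that held it, probe 1010 in 26 of 29 and probe 540 in 24 of 28. Probe 478 passed in 19 of 29 and probe 458 in 15 of 29. A count out of 28 lacks the setting without the dimmest probes, which takes out TGFB3, PLAC1 and probes 538 and 540. Being among the dimmest, these have imprecise folds. On the 12 arrays numbered 2 to 4, STAR differed by 2.06 (adjusted p = 0.000882), TGFB3 by 4.00 (0.000882) and PLAC1 by 1.68 (0.00863), whereas ANXA2 differed by 0.78 and did not pass (0.16).

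Single arrays mattered for this contrast. The count was 28 without small spherical replicate 3, 3 without filamentous replicate 3, 4 without filamentous replicate 4, and 2 with only these 2 stages in the fit. ANXA2 did not pass without small spherical replicate 1 (adjusted p = 0.0856) or 4 (0.0873) or filamentous replicate 1 (0.066), 3 (0.0944) or 4 (0.11). Nor did it pass with median centring (0.0571), array weights (0.0683), the trend along probe number removed (0.0638) or both small spherical replicate 3 and filamentous replicate 1 left out (0.0522), and it passed in 18 of 29 alternatives over a range of 0.0116 to 0.16. PLAC1 did not pass without small spherical replicate 1 (0.0639) or 4 (0.0512) or filamentous replicate 2 (0.0616), 3 (0.0745) or 4 (0.0581), over a range of 8.53e-05 to 0.152. With only these 2 stages in the fit, TGFB3 (0.143), PLAC1 (0.152) and ANXA2 (0.152) did not pass, and STAR did.

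The steroidogenesis list was higher in filamentous than in small spherical embryos, with all 8 members positive and a median of 0.87 (camera, adjusted p = 3.87e-06, and adjusted p = 0.097 with an estimated correlation). STAR passed over all probes and 5 of the 8 passed when adjusted over the list alone. CYP11A1 averaged 91.8 ± 22 (log2 1.19 ± 0.31, adjusted p = 0.097, and 0.04 without small spherical replicate 3). CYP17A1, the enzyme that leads from progestins to androgens, was dim and variable, with 4.2 ± 2 and 20.2 ± 12.7 (2.12 ± 0.76, adjusted p = 0.197). In tubular embryos the median of the list was 0.82 (adjusted p = 2.97e-07, and adjusted p = 0.0811 with an estimated correlation), and 5 of the 8 passed when adjusted over the list alone; without small spherical replicate 4 the median was 0.51. The contrasts against small spherical embryos share the same 4 arrays and are not independent of each other. On the 12 arrays numbered 2 to 4 the filamentous median was 1.10 (adjusted p = 7.99e-08), and without the dimmest 25% of probes, which takes out CYP17A1, it was 0.56 and the list was still called.

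Annexins and calcium-binding genes were higher as a group in filamentous than in small spherical embryos, with 5 of 6 members positive and a median of 0.50 (camera, adjusted p = 0.0296, and adjusted p = 0.286 with an estimated correlation). ANXA2 passed over all probes and 3 of the 6 passed when adjusted over the list alone. ANXA1 read 25.9 ± 7.14 and 54.9 ± 24.6, ANXA5 106 ± 15.8 and 144 ± 14.9 and ANXA4 22.3 ± 4.43 and 32.6 ± 5.36, none of them past the threshold over all probes. Among genes of the cytoskeleton, TAGLN2, an actin-binding transgelin (39 ± 13.4 and 73 ± 11.8), and TMSB10, a thymosin (69.1 ± 16 and 116 ± 9.9), had an adjusted p of 0.097 each (0.00863 and 0.0459 with a batch term for the arrays numbered 1, and 0.0498 for TMSB10 without tubular replicate 1). TMSB4X, another thymosin, read 140 ± 18.7 and 165 ± 36.8 (adjusted p = 0.652). These genes were named for a large F or in advance and do not stand for the cytoskeleton list, which was not called by camera. In that list 2 of the 14 measured members passed when adjusted over the list alone. The annexin list was not called on the 12 arrays numbered 2 to 4 (median 0.46, adjusted p = 0.0829), nor without small spherical replicate 1 (0.062) or 3 (0.0766) or filamentous replicate 1 (0.0766), 3 (0.0566) or 4 (0.0578). It was also lost without the dimmest 25% of probes (0.0553), with array weights (0.0526) and with the trend along probe number removed (0.0599). With the replicate number as a block it was lost too. It was called in 19 of 31 alternatives, with an adjusted p of 0.0112 to 0.286.

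Markers of the trophectoderm, the outer epithelium of the conceptus, had no member past the threshold over all probes. KRT18 read 269 ± 39.9 and 250 ± 47.4 in small spherical and filamentous embryos, KRT8 19.5 ± 4.6 and 23.9 ± 8.47 and KRT19 93.6 ± 26.6 and 135 ± 30.6 (adjusted p = 0.274). In the hypoblast list, which marks the yolk sac lineage, RBP4, the retinol carrier, read 35.9 ± 16.5 and 64.2 ± 18.1, TF 26.6 ± 6.31 and 11.5 ± 5.47 and FN1, fibronectin, 147 ± 15.1 and 191 ± 34.1. The 3 probes of RBP4 all had a positive difference, and none passed. Of the 12 measured members of the hypoblast list none passed over all probes or when adjusted over the list alone in this contrast, and neither list was called. IFNG, the interferon that pig trophoblast secretes, had 2 probes that differed in sign, -0.30 ± 0.23 for the brighter and 0.96 ± 0.55 for the dimmer, neither past the threshold. IL6 read 35 ± 8.49 and 39.3 ± 13.2, DPPA5, the 1 measured marker of the epiblast, 9.62 ± 5.11 and 18.5 ± 6.31, and the uterine genes ACP5 25.7 ± 5.98 and 19.6 ± 11.2 and PGR 4.02 ± 4.39 and 4.58 ± 4.61.

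Between small spherical and tubular embryos, STAR rose 4.04-fold (adjusted p = 0.00029), TGFB3 by a log2 difference of 3.93 ± 0.62 (adjusted p = 0.00455, 2.38 to 4.52 over the alternatives) and PLAC1 2.57-fold (adjusted p = 0.046). With probe 1010 these were the 4 of 1014 probes past the threshold by limma, all higher, with 116 at an unadjusted p below 0.05. The count was 16 without small spherical replicate 3 and 8 without filamentous replicate 1. PLAC1 passed in 11 of 28 alternatives, with a log2 difference of 0.91 to 1.58 and an adjusted p of 0.000311 to 0.155. It did not pass with median centring (0.0537), cyclic loess normalization (0.0538) or only these 2 stages in the fit (0.0817), and among single arrays left out it passed only without small spherical replicate 3 or filamentous replicate 1.

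Between large spherical and filamentous embryos, mesoderm markers were higher as a group in filamentous ones, with all 7 members positive and a median of 0.40 (camera, adjusted p = 0.0296, and adjusted p = 0.179 with an estimated correlation). This holds for the brightest probe of each gene. Against small spherical embryos, the dimmer COL3A1 probe differed by -0.815 in large spherical and -1.24 in filamentous ones, and so fell. The dimmer COL1A2 probe hardly moved (-1.44 and -1.47), and that of PDGFRB rose (-0.597 and -0.438). VIM, an intermediate filament protein of mesenchymal cells, read 28.9 ± 7.3 and 61.2 ± 21.4 (log2 1.05 ± 0.28, adjusted p = 0.61), and KDR, a receptor of vascular progenitors, 20.8 ± 1.4 and 28.2 ± 7.91. No member passed over all probes, and 1 passed when adjusted over the list alone. Against small spherical embryos the list was not called in large spherical ones (median -0.33, 5 of 7 negative, camera, adjusted p = 0.515). Nor was it called in filamentous ones (median 0.11, 4 of 7 positive, camera, adjusted p = 0.678). The list therefore shows no rise over the whole interval. No probe passed by limma, with 61 at an unadjusted p below 0.05. The list was not called on the 12 arrays numbered 2 to 4 (median 0.41, adjusted p = 0.0829), nor without large spherical replicate 2 (median 0.24, adjusted p = 0.0609), 3 (0.24, 0.0662) or 4 (0.42, 0.0645) or filamentous replicate 1 (0.22, 0.0869) or 3 (0.23, 0.0878). It was also lost with quantile (0.0662) or cyclic loess normalization (0.0531) and an offset before log2 (median 0.23, adjusted p = 0.0523). The same held for only these 2 stages in the fit (0.0503), the trend along probe number removed (0.26, 0.0714) and the replicate number as a block. The list was called in 16 of 30 alternatives, with an adjusted p of 0.0181 to 0.179.

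Over the 22 lists and 6 contrasts, 7 of 132 pairs were called by camera with the preset correlation, 0 with an estimated correlation (15 at an unadjusted p below 0.05) and 9 by fry, which asks whether the genes of a list move 1 way and compares them with no other genes. By camera with the preset correlation the count was 11 without small spherical replicate 4, 12 without tubular replicate 2, 11 without tubular replicate 4 and 4 without filamentous replicate 1. The other 17 lists had no call, and the smallest adjusted p among them was 0.0525, for extracellular matrix and integrins.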

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

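The tests of where small spherical replicate 3 and filamentous replicate 1 lie, the exchange of these 2 arrays, the fits without the arrays numbered 1 or with a batch term for them, and the test of the trend along probe number against the calls were chosen only after the results were seen.

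Within the 4 arrays of a stage, a value was singled out where its gap to the nearest other array was large against the whole range (Dixon's test). This held in 23 of 408 groups of stage and gene, and chance flags about 1 in 20 groups, here 20.4. Filamentous replicate 1 gave 5 of them: PLAC1 (17.6 against 36.4 to 41.5 in the other 3), TGFB3 (14.2 against 86.8 to 99.5), RPL36AL (394 against 173 to 195, the maximum of that array, which 7 probes share and which can be a saturated reading), ARID1A (26.2 against 11.2 to 11.7) and SLC39A2 (41.6 against 66.6 to 69.2). Tubular replicate 1 gave PLAU (54.7 against 25 to 27.1), DDX1 (4.86 against 28.8 to 37.9), SLC39A2 (86.4 against 64.2 to 67.3) and HSPE1 (152 against 106 to 111). Small spherical replicate 1 gave TAGLN2 (19.1 against 44.3 to 47.8), CCNA2 (66.4 against 22.2 to 25.4) and probe 1010 (60.2 against 45.3 to 47). Small spherical replicate 2 gave PDGFRB (70.1 against 48.9 to 51.9) and RPL23 (332 against 257 to 268), replicate 3 gave PLAC1 (18.4 against 9.39 to 10.4) and PTBP1 (20.3 against 19 to 19.2), and replicate 4 gave AHSG (62.8 against 71.8 to 73.3) and KRT8 (12.6 against 20.9 to 22.2). Large spherical replicate 1 gave TGFB3 (26.1 against 52.4 to 55) and probe 458 (64.5 against 93.3 to 99.2), replicate 2 gave DDX39B (21.4 against 39.1 to 43.4), and replicate 3 gave PSMB2 (33.7 against 43.4 to 44.7). Filamentous replicate 2 gave VCP (14.6 against 23.8 to 26.2).

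Small spherical replicate 3 lay toward the later stages and filamentous replicate 1 toward the small spherical one: on an axis over all probes from the other small spherical arrays (0) to the other later arrays (1) they lay at 0.685 and 0.641, where the other small spherical arrays lay at 0.154 to 0.555 and the other filamentous ones at 0.972 to 1.01. A swap of the 2 is argued against by the 8 steroidogenesis genes, whose mean in small spherical replicate 3 lay -4.26 SD from that of the 11 other later arrays. This list was picked after it had been called with small spherical replicate 3 counted as small spherical, so the test is not fully independent. The list was also called without both arrays. The lowest of the 12 later arrays lay at 0.576, above the bound of 0.5, but so did small spherical replicate 1, which makes this second test weak. A wrong label on small spherical replicate 3 alone stays open because the 2 tests disagree: its position of 0.685 exceeds the lowest later array, and its steroidogenesis mean lay -3.08 SD from the 12 later arrays. A wrong label on filamentous replicate 1 stays open too (1.36 SD from the mean of the 4 small spherical arrays), with an SD from only 4 arrays. Its list mean of 6.16 lay above the small spherical ones (5.19 to 5.96). It also read higher for STAR (113 against at most 50.8) and ANXA2 (201 against at most 98.9). For TGFB3 (14.2 against at most 14.5) and PLAC1 (17.6 against at most 18.4) it lay within the small spherical range. Embryos further along within the size class, or RNA of a later stage mixed in, could also place small spherical replicate 3 above 0.555, the highest of its 3 fellows, and cannot be told apart from a wrong label here because no size is given per sample.

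The 4 arrays numbered 1 stood apart from the others: a term for them passed for 172 probes, 79 higher and 93 lower, among them AIF1 (-1.90 on the log2 scale), PARVA (-1.71) and PARK7 (-2.05), named after their values were seen. A deviation that rises or falls steadily with intensity is argued against by a Spearman's rho of 0.0219 between this term and mean log2 intensity. Deviations that are larger in both directions among dim probes, or that follow intensity along a curve, were not tested. A smooth trend along probe number is argued against by the 144 of these probes that still passed after it was removed. Finer effects of position were not removed. Another make-up of the tissue stays open: the smallest adjusted p of the hypoblast, mesoderm and trophectoderm lists was 0.873, a result that the bound written beforehand took as exclusion. That bound was wrong, since a list test that misses its threshold does not exclude a shift, and the verdict was changed after the value was seen. The labels name no batch, so a separate membrane, labelling or litter for these arrays could not be tested, and no biological explanation beyond tissue make-up was tested.

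Probes with neighbouring numbers deviated together: their residuals correlated by 0.136 on average over 1005 pairs, against at most 0.0335 in 100 shuffled orders, and by 0.0779 at a distance of 10 and 0.0318 at 50. Probes of the same gene lying side by side are argued against as the cause, since the 451 neighbours with different gene names correlated by 0.116. Removing a smooth trend along probe number lowered the mean to 0.0609. The smooth trend that was removed is argued against as the whole cause of the calls, of which 15 of 17 still passed. The remaining 0.0609 exceeded the 0.0335 of the shuffled orders, so effects of position were only partly removed. Whether the rest of them contributes to the calls cannot be told from this removal. STAR, CYP11A1, ACSL3, CTSC, SMAD4 and SOD1 all lie near the end of the probe numbering. Their differences in the first step need not be independent of each other. No biological explanation was tested, and what the probe numbers stand for on the membrane is not given in the sources used here.

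Calls were counted again after the arrays had been split in other ways, with the real split included in each count. These counts take the arrays as exchangeable, and the arrays numbered 1, which stand apart, limit that. For large minus small spherical, 1 of 35 splits gave as many calls, with 4 for the real split and at most 1 for another. The numbers pair the samples in this contrast, and only 8 of these splits part each pair as the real one does, too few for a share under 0.05; the 7 others gave at most 0 calls, with or without the replicate number as a block (real 4 and 5). For tubular minus small spherical chance can be excluded only with all 8 arrays taken as exchangeable (1 of 35, 4 real, at most 0 otherwise), since only 8 splits part each pair of arrays with the same number, too few for a share under 0.05. For filamentous minus small spherical chance cannot be excluded (2 of 35, 9 real, 10 in the highest other): that other split exchanges small spherical replicate 3 and filamentous replicate 1, and its 10 calls share 2 with the real 9, PLAC1 and TGFB3, while STAR did not pass in it (adjusted p = 0.165). That split does not part the pairs. Among the 8 that do, the real one gave 9 calls and the others at most 0 (15 and 0 with the replicate number as a block), again too few splits for a share under 0.05. For the 3 contrasts without a call the count of splits decides nothing, since each split gives at least 0 calls: tubular minus large spherical (35 of 35, 0 real, at most 3), filamentous minus tubular (35 of 35, 0 real, at most 0) and filamentous minus large spherical (35 of 35, 0 real, at most 1). For the limma F test, 3 of 100 drawn splits gave as many calls (4 real), so chance can be excluded with the arrays taken as exchangeable, but the highest other split gave 48. That split puts the 4 arrays numbered 1 into 1 group and so points to a structure of the samples; with a batch term for these arrays the real split gave 10 calls and on the other 12 arrays 5. For the list shifts chance can be excluded on the same terms (1 of 100, 7 real, at most 6 otherwise), and only for the lists counted together. It is not excluded for any single list, and 3 of the 7 calls are the steroidogenesis list against the same small spherical arrays. The splits were counted with the preset correlation, and with an estimated correlation the real arrays gave 0 list calls.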

How the results depend on the processing

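The batch term for the arrays numbered 1, the 12 arrays numbered 2 to 4, the removal of the trend along probe number, and the removal of both small spherical replicate 3 and filamentous replicate 1 were chosen only after the results were seen. STAR rose under all 29 alternatives, by 1.52 to 1.93 from small to large spherical (adjusted p up to 0.0328) and by 1.72 to 2.19 from small spherical to filamentous (up to 0.00517). The steroidogenesis list was called in its 3 contrasts under each alternative but the estimated correlation. The 3 contrasts without a call (tubular minus large spherical, filamentous minus tubular, filamentous minus large spherical) had 0 under each alternative by limma, with 33, 34 and 61 probes at an unadjusted p below 0.05. Among named results 17 calls gave 486 values, of which 401 passed and 85 did not, and 99 without a call gave 2842, of which 42 passed; no called direction was reversed. With no blank features, signal over background is unknown, and folds of dim probes are imprecise.

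The values that moved were as follows, and the cause was not tested unless given. Leaving out the dimmest 25% of probes takes out TGFB3, PLAC1 and probes 538 and 540, and also means fewer tests. The F test then had 2 calls, and TGFB3 and probe 538, called in the main fit, were no longer tested. Large minus small spherical had 7, tubular minus small spherical 13 and the lists 4. An offset of 9.07 before log2 gave 13 for tubular minus small spherical. With only the 2 stages compared in the fit, which leaves fewer arrays, filamentous minus small spherical had 2. Array weights gave 7 for the F test and 29 for tubular minus small spherical. A variance trend with a robust prior gave 9 for large minus small spherical, 14 for tubular minus small spherical and 12 for the lists. The batch term gave 10 for the F test, 7 for large minus small spherical and 14 for filamentous minus small spherical. The 12 arrays gave 4 list calls. Removing the trend along probe number gave 8 for large minus small spherical and 4 for the lists. Without both small spherical replicate 3 and filamentous replicate 1 the F test had 17 calls, large minus small spherical 36, filamentous minus small spherical 31, tubular minus small spherical 29 and the lists 4. An estimated correlation gave 0 list calls by camera (15 at an unadjusted p below 0.05; fry gave 9). Leaving out 1 array gave 1 to 13 calls in the F test (lowest without small spherical replicate 2, highest without replicate 3), 1 to 26 for large minus small spherical (lowest without small spherical replicate 2 or 4 or large spherical replicate 2, 3 or 4, highest without small spherical replicate 3), 3 to 28 for filamentous minus small spherical (without filamentous replicate 3 and small spherical replicate 3), 3 to 16 for tubular minus small spherical (lowest without any of 11 arrays, highest without small spherical replicate 3) and 4 to 12 for the lists (filamentous replicate 1 and tubular replicate 2).

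With the replicate block, the F test had 10 calls, filamentous minus small spherical 15, tubular minus small spherical 11 and the lists 4. With it ACSL3 passed from small to large spherical (adjusted p = 0.0138), and ADSL (0.0277), TMSB10 (0.0277) and TAGLN2 (0.0232) from small spherical to filamentous, while the mesoderm (0.0657), annexin (0.0679) and ribosomal (0.0655) lists were not called. In the main fit over the 4 stages the numbers were not taken to pair the samples. All 6 correlations between deviations of arrays numbered 1 exceeded 0.1, and 3, 5 and 3 of 6 did for numbers 2, 3 and 4. Between different numbers 15 of 72 did. The median correlation was 0.447, 0.127, 0.167 and 0.153 for numbers 1 to 4, against -0.0895 between different numbers. With 13 of 16 arrays correlating best with their own number, a pairing over all stages stays possible. The values with the block would then apply.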

Other observations

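All genes of this part were chosen after their values were seen, and the test of the difference between steps was added then too. PDPN, a mucin-type membrane glycoprotein, read 148 to 203 in large spherical embryos and 162 to 230 in tubular ones, against 54.8, 22.2, 163 and 12.6 in small spherical replicates 1 to 4 (filamentous minus small spherical, log2 2.14 ± 0.55, limma adjusted p = 0.097). PTGES, which makes prostaglandin E2, read 112 to 119 in large spherical embryos and 54.8, 47.8, 80.3 and 56.2 in small spherical replicates 1 to 4 (log2 0.99, adjusted p = 0.11). ESR2, an oestrogen receptor, read 34.6 in small spherical replicate 3 and 3.91 to 12.6 in the other 3 (filamentous minus small spherical, adjusted p = 0.17). SFN, an epithelial 14-3-3 protein, read 154 there and 61.7 to 92.3 in the others. In filamentous replicate 1, PDPN read 115, PTGES 59.5, ESR2 14.2 and SFN 67.2, each below the other 3 filamentous arrays. The 4 genes passed for filamentous minus small spherical when this array and small spherical replicate 3 were exchanged. Such a call favours genes high in small spherical replicate 3 and low in filamentous replicate 1. Their values are therefore no separate evidence about these 2 arrays. None of the 4 genes passed in filamentous or large spherical minus small spherical over the 16 arrays.

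Genes of cholesterol and lipid transport moved together from tubular to filamentous embryos by fry, with 7 of 10 positive and a median log2 difference of 0.31 (adjusted p = 0.0048), but were not called by camera (adjusted p = 0.106), and none passed when adjusted over the list alone.

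For STAR, the log2 difference of the first step minus that from large spherical to filamentous embryos was 1.51 ± 0.40, which did not pass (limma, adjusted p = 0.29). No probe passed this test, with 61 at an unadjusted p below 0.05 where chance gives 50.7.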
